A study of Rattus norvegicus with 6 samples.

How the data were processed

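Brains of newborn rats from calorically restricted (CR) and control dams were compared, with 3 libraries per group and 1 table per library. Per the labels' protocols, RNA was extracted with TRIzol and libraries of polyadenylated RNA were made with a stranded QIAseq kit and an MGIEasy conversion kit. Per the submitters' processing notes, the tools were Trim Galore 0.4.4, Trimmomatic 0.36, cutadapt 1.16, STAR 2.7.10a and featureCounts 2.0.1, and the genome build was mRatBN7.2; the notes give no order, role or settings. The strand setting of the counting is not given in the sources used here, so reads of overlapping genes on opposite strands may not have been told apart.

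The deposited values were FPKM per Ensembl gene, made by the authors and given per the file headers with an exon length for each of the 30498 genes. In each table FPKM times length summed to the same total, and 100% of the values were whole multiples (within 0.05) of a single step, the worth of 1 read, so the reads assigned to each gene and the depth of each library could be worked out. Depth was 14030961, 25345354 and 18429571 assigned reads for control replicates 1 to 3 and 22161522, 25734737 and 25690833 for CR replicates 1 to 3. A gene with 1 kb of exon and 3 reads was at 0.117 to 0.214 FPKM. Floors of this kind cover counting error only. The 10 genes with most reads took 4.17% to 4.66% of the reads of a library, and genes with under 200 nt of exon took 0.108% to 0.130%. No gene of the mitochondrial chromosome was in the tables used here.

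Symbols came from the tables, which named 23359 of the genes; 17161 of these symbols were official symbols in the RefSeq annotation of assembly GRCr8, which was used only for names and synonyms. Coordinates are those of the deposited tables, on mRatBN7.2. Where several IDs had 1 symbol, the ID with the highest mean was used. Replicates of a group differed by more than counting noise, with a mean chi-square per gene of 6.63 to 15.6 over genes with at least 50 reads in a pair (1 for noise alone), so no library was counted as a repeat of another.

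Genes with a mean of at least 0.5 FPKM over the 6 libraries were tested (15247 genes) with limma 3.58.1 in R 4.3.3. The model was fitted to log2(FPKM + 1) with group as its only term and moderated with a trend on the mean, tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 fold changes are CR minus control on that scale, which understates the change of low genes. Folds are ratios of group means of FPKM; where a group had no read at all, the fold was computed against the FPKM that 3 reads in each of its libraries would give and is a lower bound.

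Gene lists (33, of which 29 had at least 3 tested members) were fixed before the data were examined and tested with camera in limma with a preset correlation between genes of 0.01, adjusted over the 29 lists, and again with an estimated correlation. For each list, members past the threshold are counted both over all genes tested and adjusted over the list alone. Genes named in the text were chosen by a rule fixed at the same time. The rule took up to 12 higher and 12 lower genes with the largest log2 fold changes among those past the threshold with a mean of at least 1 FPKM, an official symbol and groups that do not overlap; for each list the leading members past the threshold by log2 fold change, up to 4 (or, if none passed, up to 2 by p), of which the text gives the first few; and Insr, Igf1r, Igf1, Igf2, Irs1, Irs2, Slc2a1 and Slc2a3 in any case. Markers of brain regions were listed after the main comparison had been seen, from general knowledge of neuroanatomy, with a record of which had been seen; markers with a mean of at least 0.1 FPKM were used, and those named in the text fall outside the rule.

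The test was run on simulated FPKM for 15247 tested genes drawn with the depths of the real libraries and a dispersion of 0.01. It called 0% of genes changed 1.25-fold, 24% of those changed 1.50-fold, 92% of those changed 2-fold and 100% of those changed 4-fold in the right direction. Of its 119 calls in that draw, 13 (10.9%) fell on unchanged genes. Over 10 further draws 8.60% of its calls on average did so (7.26% to 10.7%), above the nominal 5%. The list test called a list of 20 genes shifted 1.25-fold and 0 of 20 unchanged lists. Simulated genes were drawn independently, whereas estimated correlations in the real lists reached 0.70. The simulation therefore does not show how the preset correlation performs on lists whose members vary together.

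Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter on low values, a mean of at least 2 FPKM, median-ratio size factors, quantile normalization, limma without the trend, robust limma, the replicate number as a block, camera with an estimated correlation, and leaving out each library. Added after the data were seen were limma-voom on the reads worked out from the FPKM and a covariate for presence of Y-linked RNA. Isoforms were not analysed here, and some genes that the rule selects are not reported here. Figures were drawn with matplotlib 3.10.9.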

Results

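The study measured polyadenylated RNA from brains of newborn rats (Rattus norvegicus) whose mothers were either fed normally (control) or kept on caloric restriction (CR), a model of fetal growth restriction in which the pups were delivered by Caesarean section and the brain was taken at once. Each group had 3 libraries, and the labels describe all 6 as whole brain. Nothing in the labels says whether the 3 libraries of a group came from separate pups or litters, so p-values measure the spread between these libraries. Gene expression was given as FPKM for 30498 Ensembl genes, of which 23944 had a value above 0 in some library. The reads assigned to genes, worked out from the FPKM and the gene lengths, came to 14030961, 25345354 and 18429571 for control replicates 1 to 3 and to 22161522, 25734737 and 25690833 for CR replicates 1 to 3. For a gene with 1 kb of exon, 3 reads corresponded to between 0.117 and 0.214 FPKM, depending on the library. Values per group below are means ± SD in FPKM over the 3 libraries of a group.

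The comparison of CR with control asked how the transcriptome of the growth-restricted brain differed at birth. The largest increases in CR included genes of regions caudal to the telencephalon, the forebrain part that holds the cortex and the striatum, and the largest decreases included genes of cortical excitatory neurons. The 12 largest increases among genes with at least 1 FPKM included Pmch, which encodes melanin-concentrating hormone of the lateral hypothalamus (0.723 ± 0.511 FPKM in control and 20.9 ± 6.60 in CR), and Avp, which encodes vasopressin (1.86 ± 0.894 and 17.6 ± 2.14 FPKM). They also held the transcription factor genes Shox2 (0.431 ± 0.298 and 12.7 ± 0.877 FPKM) and Tcf7l2 (8.78 ± 6.33 and 52.7 ± 13.3 FPKM), both expressed in the developing thalamus, and Barhl1 (0.0697 ± 0.0419 and 7.84 ± 0.902 FPKM), which is expressed in cerebellar granule cell precursors. The developmental regulator genes Mab21l2, Mab21l1, Ebf3, Tfap2b, Irx1 and Irx2 and the synuclein gene Sncg completed that set, with log2 fold changes from 2.75 for Irx2 to 3.73 for Mab21l2 (SE 0.193, limma adjusted p = 0.000132). On mRatBN7.2, Mab21l2 (ENSRNOG00000031398) lies on chromosome 2 from 171946573 to 171949655. Among the 12 largest decreases, Neurod6 (199.9 ± 32.2 and 83.7 ± 18.8 FPKM), Bhlhe22 (125 ± 3.52 and 50.7 ± 9.12 FPKM), Emx1 (17.1 ± 3.13 and 6.29 ± 1.81 FPKM) and Mef2c (89.9 ± 23.3 and 34.7 ± 8.65 FPKM) are transcription factor genes of cortical neurons and their precursors. Zeb2 (log2 fold change -1.41, SE 0.167, adjusted p = 0.00137), Mpped1, Inhba, Ntsr1, Tmem74 and Mir3099 were also in that set, with log2 fold changes between -1.42 and -1.26. The call for Mir3099, a microRNA gene with 129 nt of exon, was lost without CR replicate 1 (adjusted p = 0.0696) and without CR replicate 3 (adjusted p = 0.0616) and with no filter on low values (adjusted p = 0.0610).

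Of 15247 genes tested with limma, 5173 (33.9%) passed an adjusted p of 0.05, 2706 of them higher and 2467 lower in CR. Counts of list members below are to be read against that share, which genes picked at random would give on average. The median absolute log2 fold change of these genes was 0.41, and 288 rose and 55 fell by at least 1 on the log2 scale. In 7676 genes (50.3%) the values of the groups did not overlap, against 10% by chance. Without CR replicate 2 the count was 3210, and without CR replicate 3 it was 3308.

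Regional markers were then examined with a list of genes written after the main comparison had been seen. All 55 markers of thalamus, hypothalamus, midbrain, hindbrain and cerebellum with a mean of at least 0.1 FPKM had their 3 CR values above their 3 control values. Some had been seen to be higher before they were listed, and among the 35 whose values had not been seen it held for 35. Chance would give 5% in that direction for each gene, but 50.3% of all tested genes did not overlap in one direction or the other. The 35 are also not independent, since some, such as Hoxb5, are relatives of a marker that had been seen (Hoxc4). The FPKM of the 11 midbrain markers summed to 1.81 ± 0.368 in control and to 38.2 ± 4.47 in CR, a 21.1-fold difference. Tyrosine hydroxylase (Th), the enzyme that makes dopamine precursors, was at 0.485 ± 0.210 and 7.93 ± 1.20 FPKM, and Pou4f2 had no read in any control library and 3.96 ± 0.572 FPKM in CR, at least 77.1-fold higher than 3 reads in each control library would give. The 8 cerebellar markers summed to 2.7 ± 1.06 and 40.2 ± 6.83 FPKM, the 13 hypothalamic markers to 5.76 ± 0.859 and 57.3 ± 10.9 FPKM, and the 4 thalamic markers to 13.3 ± 8.80 and 87.8 ± 19 FPKM. The 19 hindbrain markers summed to 0.732 to 0.959 FPKM in the control libraries and to 24.2, 23.9 and 86.9 FPKM in CR replicates 1 to 3. CR replicate 3 stood apart in Hox genes of the caudal hindbrain and cervical cord, with Hoxb5 at 14.4 FPKM against 0.559 and 0.405 FPKM in CR replicates 1 and 2 and no read in control. Tph2, the serotonin-synthesis enzyme of the raphe nuclei, was at 0.22 ± 0.00955 and 5.27 ± 0.745 FPKM. In the telencephalon, 10 of 10 dorsal markers and 13 of 14 ventral markers had their 3 CR values below their 3 control values. The exception, Six3, had them above but did not pass the threshold (limma adjusted p = 0.0741). The 10 dorsal markers summed to 723 ± 95 FPKM in control and to 304 ± 67.5 in CR, a 2.38-fold difference, and the 14 ventral markers to 176 ± 19 and 108 ± 5.08 FPKM. Regional marker levels and feeding differed between the same libraries, so no difference between the groups reported here, in Insr, Igf1r, Igf2, the gene lists or the 5173 genes, was separated from that in regional markers.

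**Figure D1:**
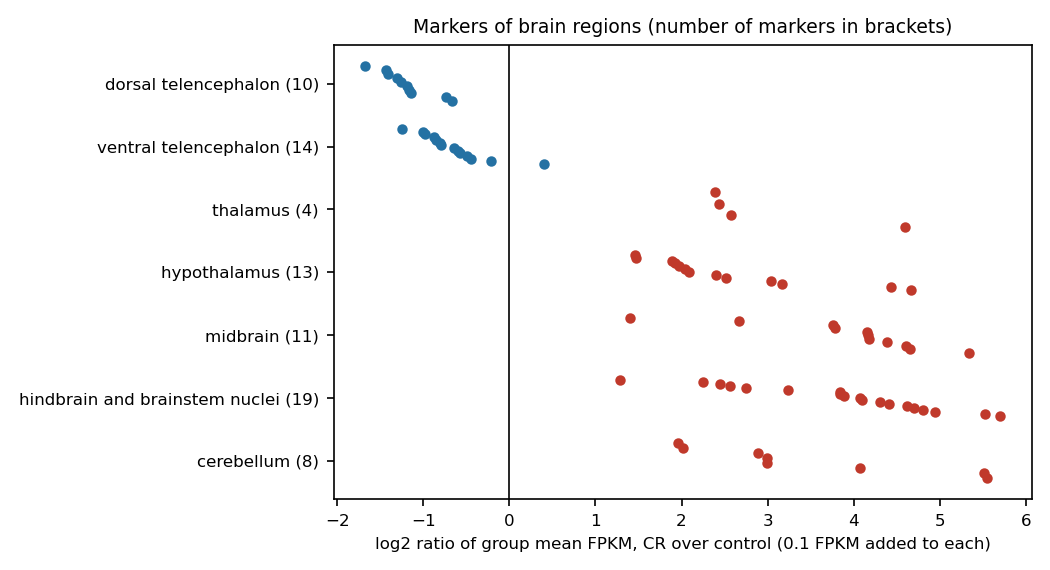
Each point is 1 marker gene, placed by the log2 ratio of its mean FPKM in CR (n = 3) over control (n = 3) after adding 0.1 FPKM to each mean, with regions on the vertical axis and the number of markers in brackets. The 55 markers of regions caudal to the telencephalon lie to the right of 0, and 10 of 10 dorsal and 13 of 14 ventral telencephalic markers lie to the left.

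The title of the study concerns the insulin receptor, so Insr and its relatives were examined in every library. Insr (ENSRNOG00000029986) lies on chromosome 12 from 1197100 to 1330883, Igf1r (ENSRNOG00000014187) on chromosome 1 from 121550743 to 121831777 and Igf2 (ENSRNOG00000020369) on chromosome 1 from 197814410 to 197823018. Insr was at 5.57, 6.0 and 6.50 FPKM in control replicates 1 to 3 and at 5.31, 4.50 and 4.98 FPKM in CR replicates 1 to 3, from 423 to 823 reads per library. Its log2 fold change of -0.24 (SE 0.0885) did not pass the threshold (limma adjusted p = 0.0682). It passed with limma-voom on the reads worked out from the FPKM (-0.30, adjusted p = 0.0259) and with presence of Y-linked RNA as a covariate (-0.30, adjusted p = 0.0354). Gene-level values do not separate isoforms A and B of the receptor, which differ by an alternative exon, so isoform use was not analysed here. Igf1r, the receptor for insulin-like growth factor I, fell from 6.01 ± 0.486 to 3.88 ± 0.377 FPKM (log2 fold change -0.52, SE 0.0944, adjusted p = 0.00561), and the receptor substrate gene Irs2 fell from 5.95 ± 0.119 to 4.50 ± 0.167 FPKM (-0.34, SE 0.0716, adjusted p = 0.0102). Igf2, the fetal growth factor, rose from 21.3 ± 6.85 to 40.1 ± 3.70 FPKM (0.92, SE 0.211, adjusted p = 0.0135). Igf1 was at 3.54 ± 2.63 and 5.82 ± 1.04 FPKM (0.72, SE 0.342, adjusted p = 0.140). Control replicate 1 set that result, since without it the log2 fold change of Igf1 was 1.17 with an adjusted p of 0.00442, and limma-voom gave 1.06 (adjusted p = 0.0228). Irs1 (adjusted p = 0.672) and the glucose transporter genes Slc2a1 (24.6 ± 2.15 and 23.8 ± 3.49 FPKM, adjusted p = 0.731) and Slc2a3 (15.1 ± 2.81 and 13.8 ± 1.17 FPKM, adjusted p = 0.520) did not pass. Of 41 tested genes of insulin and IGF signalling, 5 were higher, 8 were lower and 28 did not pass (5 higher and 7 lower adjusted over the list alone), and the list as a whole did not pass the camera test (adjusted p = 0.192). Its higher members were led by Igf2, by Igfbp5 (26.6 ± 7.81 and 45.0 ± 4.94 FPKM), which encodes an IGF-binding protein, and by Grb10 (9.71 ± 1.99 and 15.3 ± 0.553 FPKM), an imprinted adaptor that restrains insulin receptor signalling. The Igfbp5 call was lost without CR replicate 1 (adjusted p = 0.0572), without CR replicate 2 (0.0712) and with no filter on low values (0.0520). In the same CR libraries the summed markers of the 5 caudal regions stood at 226 to 291 FPKM, against 15.7 to 31.8 FPKM in control. Meningeal and choroid plexus markers had median log2 fold changes of 0.32 and 0.35, though neither list passed the main camera test. The changes of Igf2 and Igfbp5 were not separated from these either.

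**Figure D2:**
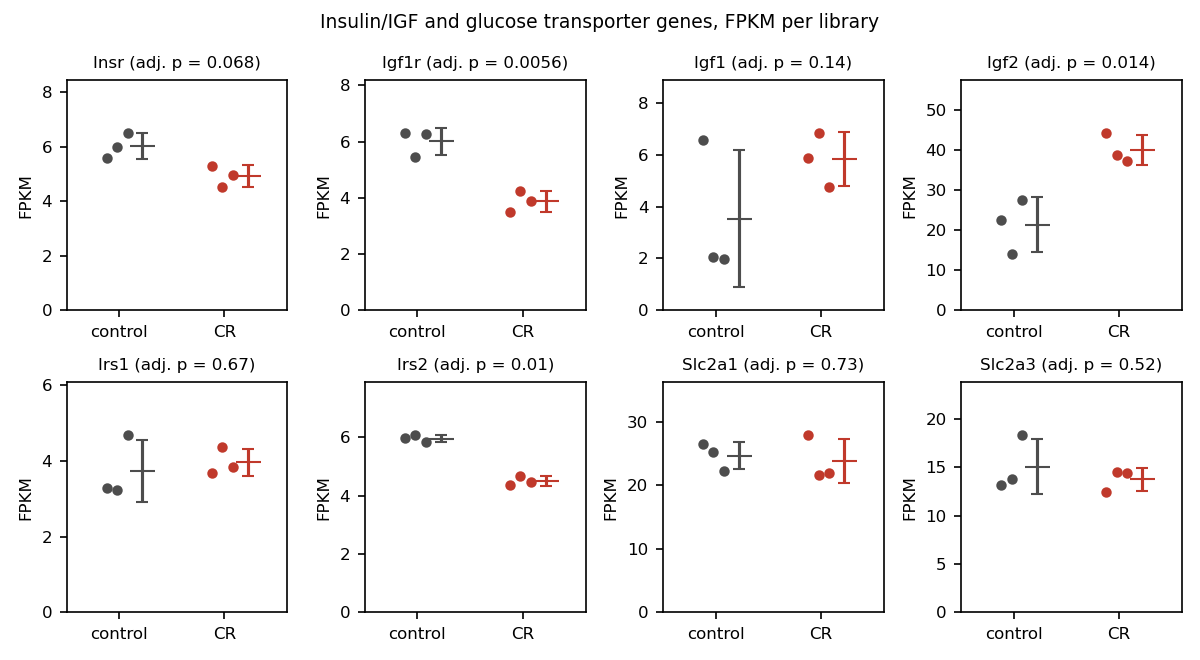
FPKM of 8 genes of insulin and IGF signalling and glucose transport in each of the 3 control (grey) and 3 CR (red) libraries, 1 panel per gene with its own vertical axis from 0. Points are libraries, bars are means ± SD, and the limma adjusted p stands above each panel. Igf1r and Irs2 were lower and Igf2 higher in CR, and Insr had an adjusted p of 0.0682.

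A list that mixes regulators of the alternative exon of Insr with neural splicing factors had more members past the threshold as lower than as higher. Its counts do not separate the regulators of Insr from the other members. Of 24 tested members 1 was higher, 13 were lower and 10 did not pass (4 higher and 15 lower adjusted over the list alone). The list passed the camera test with a preset correlation (adjusted p = 0.00479) but not with an estimated one (adjusted p = 0.405 with an estimated correlation). Celf2, an RNA-binding protein gene of the CUG-binding family, fell from 90.1 ± 6.97 to 53 ± 2.26 FPKM (log2 fold change -0.75, SE 0.0649, adjusted p = 0.000533), and the SR protein gene Srsf7 fell from 101 ± 8.50 to 73.6 ± 1.12 FPKM. Nova1, a neuronal splicing factor gene that is strongly expressed in hypothalamus, hindbrain and spinal cord, was the 1 member past the threshold over all genes as higher, rising from 11 ± 1.43 to 34.9 ± 2.10 FPKM (1.58, SE 0.0913, adjusted p = 0.000138). These shifts went together with the 2.38-fold lower sum of dorsal telencephalic markers in CR.

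Nuclear genes of oxidative phosphorylation and genes of glycolysis had more members past the threshold as higher than as lower in CR. Among 30 tested nuclear genes of oxidative phosphorylation, 26 were higher, none was lower and 4 did not pass (28 higher adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 4.68e-07, and adjusted p = 0.405 with an estimated correlation). Sdhc, a subunit of complex II, rose from 74.5 ± 1.65 to 101 ± 2.80 FPKM and Ndufa4 from 187 ± 6.84 to 249 ± 16.4 FPKM. Of 25 genes of glucose transport and glycolysis, 13 were higher, 1 was lower and 11 did not pass (14 and 1 adjusted over the list alone). For glycolysis camera gave an adjusted p of 0.000526, and adjusted p = 0.405 with an estimated correlation. The neuronal enolase gene Eno2 rose from 58.3 ± 0.850 to 94.2 ± 3.83 FPKM and Aldoc, an aldolase gene of astrocytes and Purkinje cells, from 116 ± 5.62 to 187 ± 8.84 FPKM. Ketone and fatty acid oxidation genes had 5 members higher, none lower and 19 not past the threshold (5 adjusted over the list alone). For the ketone list camera gave an adjusted p of 0.0408, and adjusted p = 0.613 with an estimated correlation. Acadm, the medium-chain acyl-CoA dehydrogenase, rose from 7.52 ± 1.54 to 13.1 ± 0.447 FPKM and the coactivator gene Ppargc1a from 2.16 ± 0.3 to 4.07 ± 0.329 FPKM. That list's call was lost without control replicate 2 (adjusted p = 0.112), without CR replicate 1 (0.0673), without CR replicate 3 (0.0519) and with the Y-linked covariate (0.0570). Cholesterol biosynthesis had 3 members higher, 5 lower and 14 not past the threshold (4 and 5 adjusted over the list alone). For cholesterol biosynthesis camera gave an adjusted p of 0.821, with a median log2 fold change of 0.04. Its largest change was in Tm7sf2, a sterol reductase gene (9.04 ± 0.7 and 12.6 ± 1.59 FPKM), whose call was lost without CR replicate 2 (adjusted p = 0.0561) and without CR replicate 3 (0.0550), and Insig1, a sterol sensor, rose from 16.9 ± 0.942 to 21.6 ± 0.317 FPKM. All 26 listed symbols of mitochondrially encoded genes were absent from the tables used here, and that list was not analysed here. In the same comparison the median log2 fold change of astrocyte markers was 0.60, and the summed hypothalamic markers were 9.95-fold higher in CR.

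Of 19 tested imprinted growth genes, 15 were higher, none was lower and 4 did not pass (15 higher adjusted over the list alone), with a median log2 fold change of 0.62 (camera adjusted p = 8.27e-05, and adjusted p = 0.499 with an estimated correlation). Dlk1, a Notch-family ligand gene, rose from 4.24 ± 1.37 to 18.4 ± 1.64 FPKM (log2 fold change 1.92, SE 0.171, adjusted p = 0.000577). H19 rose from 19.3 ± 5.41 to 49.6 ± 5.48 FPKM, Peg10 from 9.03 ± 0.0829 to 21.8 ± 2.67 FPKM, and Peg3 from 36.9 ± 7.03 to 72.4 ± 8.61 FPKM. Hypothalamic markers, summed over 13 genes, were 9.95-fold higher in the same CR libraries, and the median log2 fold change of meningeal markers was 0.32.

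Among progenitor, cell cycle and ribosomal protein genes, the members past the threshold were lower in CR with 1 exception, and many members did not pass. Of 22 neural progenitor and neuroblast markers 12 were lower, 1 was higher and 9 did not pass (12 and 1 adjusted over the list alone). For progenitor markers camera gave an adjusted p of 0.00184, and adjusted p = 0.414 with an estimated correlation. After Neurod6, the largest decreases were in the neuroblast transcription factor gene Sox11 (114 ± 10.7 and 55.2 ± 7.54 FPKM), in the fetal RNA-binding protein gene Igf2bp1 (3.33 ± 0.820 and 1.21 ± 0.387 FPKM) and in the proneural gene Neurog2 (4.57 ± 0.477 and 1.98 ± 0.364 FPKM). Of 29 cell cycle genes 7 were lower, none was higher and 22 did not pass (5 lower adjusted over the list alone; camera adjusted p = 0.00797, and adjusted p = 0.618 with an estimated correlation), among them the replication helicase gene Mcm4 (13.4 ± 0.498 and 8.0 ± 0.957 FPKM) and the cyclin gene Ccnd2 (35.7 ± 3.00 and 25.3 ± 2.87 FPKM). Ribosomal protein genes had 2 of 40 members lower, none higher and 38 not past the threshold, and none passed when adjusted over the list alone. Many ribosomal protein genes have near-identical pseudogenes that can share their reads. The ribosomal list passed with the preset correlation (camera adjusted p = 0.0262) but not with an estimated one (adjusted p = 0.695 with an estimated correlation), and it was lost without control replicate 2 (adjusted p = 0.140), without CR replicate 3 (0.217), with a filter at a mean of 2 FPKM (0.0778) and with the Y-linked covariate (0.102). In the same comparison the median log2 ratio of means of the dorsal telencephalic markers, which include Neurod6, was -1.22.

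Among markers of astrocytes, oligodendrocytes, neurons and microglia, more members passed as higher than as lower in CR, and many did not pass. Astrocyte markers had 12 of 18 members higher, none lower and 6 not past the threshold (13 higher adjusted over the list alone). For astrocyte markers camera gave an adjusted p of 6.69e-05, and adjusted p = 0.414 with an estimated correlation. Agt, the angiotensinogen gene, rose from 1.92 ± 1.36 to 12 ± 3.58 FPKM and the calcium-binding protein gene S100b from 9.78 ± 3.07 to 44.7 ± 6.23 FPKM. Oligodendrocyte and myelin markers had 7 of 16 higher, none lower and 9 not past the threshold (9 higher adjusted over the list alone). For myelin markers camera gave an adjusted p of 0.00206, and adjusted p = 0.414 with an estimated correlation. Mag, the myelin-associated glycoprotein gene, rose from 0.511 ± 0.213 to 2.74 ± 0.824 FPKM and Gpr17, a receptor gene of maturing oligodendrocyte precursors, from 3.68 ± 0.210 to 7.10 ± 0.886 FPKM. Neuron and synapse markers had 13 of 25 higher, 4 lower and 8 not past the threshold (13 and 4 adjusted over the list alone). For neuronal markers camera gave an adjusted p of 0.0201, and adjusted p = 0.618 with an estimated correlation, and their list lost its call without control replicate 1 (adjusted p = 0.0582). The neurofilament genes Nefl (20.02 ± 3.08 and 90.8 ± 15.3 FPKM) and Nefh (1.24 ± 0.137 and 7.39 ± 2.48 FPKM) rose, as did Slc17a6, the glutamate transporter of thalamic and brainstem neurons (13.5 ± 2.83 and 51.6 ± 7.95 FPKM). Microglia markers had 6 of 17 higher, none lower and 11 not past the threshold (9 higher adjusted over the list alone). For microglia markers camera gave an adjusted p of 0.000906, and adjusted p = 0.414 with an estimated correlation. The complement gene C1qb rose from 12.8 ± 1.99 to 20.2 ± 1.64 FPKM, and C1qa was at 7.05 ± 1.34 and 11 ± 1.73 FPKM, with its call lost without CR replicate 1 (adjusted p = 0.0561). These cell type markers stood in libraries whose caudal marker sums were 226, 291 and 289 FPKM for CR and 15.7, 25.6 and 31.8 FPKM for control.

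Markers of vessels, blood and the brain's coverings did not pass as lists in the main test. Endothelial and pericyte markers had 2 members higher, 1 lower and 14 not past the threshold (2 and 1 adjusted over the list alone). For endothelial markers camera gave an adjusted p of 0.344. The phospholipid transfer protein gene Pltp was at 12.2 ± 2.01 and 19.7 ± 1.14 FPKM. Choroid plexus markers had 1 of 14 higher, the transcription factor gene Otx2 (2.87 ± 0.891 and 10.3 ± 3.52 FPKM), which is also expressed in midbrain and cerebellum, and 13 not past the threshold (1 adjusted over the list alone; camera adjusted p = 0.0820). The choroid plexus list passed without control replicate 1 (adjusted p = 0.000470), with size factors (0.0491), with limma-voom (0.0219), with the Y-linked covariate (0.0135) and with replicate numbers as a block (0.0480), all at the preset correlation, and had adjusted p = 0.695 with an estimated correlation on all libraries. Meninges and fibroblast markers had 3 higher, none lower and 15 not past the threshold (1 adjusted over the list alone). For meningeal markers camera gave an adjusted p of 0.0514. Their list passed without control replicate 1 (0.0290), without control replicate 3 (0.00802), without CR replicate 3 (0.0245) and in other settings at the preset correlation, and had adjusted p = 0.695 with an estimated correlation on all libraries. Slc6a13, a GABA transporter gene of the meninges, was at 6.92 ± 3.24 and 14.9 ± 1.62 FPKM, and it lost its call without any 1 of the CR replicates (adjusted p from 0.0664 to 0.0809) and had a log2 fold change of 0.70 without control replicate 2, against 1.10 with all libraries. Erythroid markers had 1 of 10 lower and 9 not past the threshold (none adjusted over the list alone; camera adjusted p = 0.727). That member, Hba-a3 (3.08 ± 0.972 and 1.44 ± 0.564 FPKM), is 1 of several near-identical globin genes that can share reads, and its call was lost without control replicate 1 (adjusted p = 0.0864), control replicate 2 (0.0669), CR replicate 2 (0.0835) or CR replicate 3 (0.101).

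Among hypothalamic, pituitary and muscle genes, more members passed as higher than as lower in CR. Of 17 tested hypothalamic neuropeptide and appetite genes 12 were higher, 2 were lower and 3 did not pass (12 and 2 adjusted over the list alone). For hypothalamic genes camera gave an adjusted p of 0.000771, and adjusted p = 0.414 with an estimated correlation. Besides Pmch and Avp, Oxt, which encodes oxytocin, rose from 0.481 ± 0.468 to 3.23 ± 1.18 FPKM and the galanin gene Gal from 0.728 ± 0.260 to 3.44 ± 0.805 FPKM. In the same CR libraries the summed midbrain markers, none of which is in that list, were 21.1-fold higher. The summed hypothalamic markers were 9.95-fold higher. They share the tested members Agrp, Pmch, Trh, Avp, Oxt and Ghrh with that list, and also Hcrt, which was too low to be tested. Pituitary hormone markers had 4 of 5 tested members higher and 1 not past the threshold (4 adjusted over the list alone). For pituitary markers camera gave an adjusted p of 0.0149, and adjusted p = 0.414 with an estimated correlation. Cga, the common subunit of the pituitary glycoprotein hormones, was at 3.57, 3.89 and 0.407 FPKM in CR replicates 1 to 3 and at 0.0541 ± 0.0937 FPKM in control, and its call was lost without control replicate 1 (adjusted p = 0.0656), control replicate 2 (0.0697), CR replicate 1 (0.0859) or CR replicate 2 (0.0930). Tshb, the thyrotropin subunit, had no read in control and was at 1.21, 1.87 and 0.278 FPKM in CR replicates 1 to 3, and its call was lost without any 1 of the control replicates (adjusted p from 0.0532 to 0.0605). Skeletal muscle and bone markers had 9 of 12 higher, 1 lower and 2 not past the threshold (10 and 1 adjusted over the list alone). For muscle markers camera gave an adjusted p of 0.00183, and adjusted p = 0.414 with an estimated correlation, and the list lost its call with a filter at a mean of 2 FPKM (adjusted p = 0.287). Tnnc2, fast muscle troponin C, was at 1.39, 5.40 and 2.13 FPKM in CR replicates 1 to 3 and at 0.497 ± 0.385 FPKM in control, with its call lost without control replicate 1 (0.0684), control replicate 2 (0.0731) or CR replicate 3 (0.0531). The myosin light chain gene Myl1 rose from 0.198 ± 0.00170 to 1.38 ± 0.718 FPKM. Only 1 pineal marker was tested, Gngt1, at 0 FPKM in the control libraries and at 0.0904, 3.82 and 0 FPKM in CR replicates 1 to 3 (adjusted p = 0.292).

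Stress and hormone responses were mixed. Immediate early genes had 7 of 19 lower, 1 higher and 11 not past the threshold (8 and 1 adjusted over the list alone). For immediate early genes camera gave an adjusted p of 0.0153, and adjusted p = 0.414 with an estimated correlation. The orphan nuclear receptor genes Nr4a3 (16.3 ± 0.265 and 6.82 ± 0.954 FPKM) and Nr4a2 (21.8 ± 2.66 and 11.9 ± 1.20 FPKM) fell. Hypoxia response genes had 5 higher, 6 lower and 13 not past the threshold (5 and 6 adjusted over the list alone; camera adjusted p = 0.821), with Ndrg1 falling from 36.9 ± 3.21 to 20.5 ± 2.88 FPKM and Aldoc rising. Glucocorticoid response genes had 3 higher, 3 lower and 15 not past the threshold (3 and 3 adjusted over the list alone). For glucocorticoid genes camera gave an adjusted p of 0.821. The repressor gene Bcl6 fell from 7.22 ± 0.929 to 3.52 ± 0.348 FPKM, and the imprinted cell cycle inhibitor gene Cdkn1c rose from 23 ± 3.35 to 41.9 ± 4.85 FPKM. Integrated stress and amino acid response genes had 5 higher, 2 lower and 15 not past the threshold (5 and 2 adjusted over the list alone; camera adjusted p = 0.344), led by Phgdh, the first enzyme of serine synthesis (17.7 ± 2.45 and 32.8 ± 0.771 FPKM). Unfolded protein response genes had 1 higher, 4 lower and 13 not past the threshold (1 and 4 adjusted over the list alone). For the unfolded protein list camera gave an adjusted p of 0.0820. That list passed without control replicate 1 (0.0337), without control replicate 2 (0.0214), with no filter (0.0283) and with the Y-linked covariate (0.0203), all at the preset correlation, and had adjusted p = 0.695 with an estimated correlation on all libraries. The co-chaperone gene Dnajb9 fell from 10.004 ± 0.497 to 7.60 ± 0.428 FPKM. In p53 response and apoptosis, 2 genes were higher, 3 were lower and 13 did not pass (2 and 3 adjusted over the list alone; camera adjusted p = 0.586), and the mean log2 fold change (0.01) and the median (-0.05) differed in sign. Phlda3 rose from 2.82 ± 0.202 to 6.94 ± 0.609 FPKM and Bbc3 fell from 11.7 ± 1.69 to 7.98 ± 0.197 FPKM. Interferon and inflammation genes had 3 of 10 higher and 7 not past the threshold (5 higher adjusted over the list alone). For interferon genes camera gave an adjusted p of 0.0175, and adjusted p = 0.405 with an estimated correlation. That list was lost without CR replicate 1 (adjusted p = 0.0556), with quantile normalization (0.0576) and with a filter at a mean of 2 FPKM (0.344). The chemokine gene Ccl3, at 0.598 ± 0.243 and 1.28 ± 0.104 FPKM, lost its call without control replicate 2 (0.0563) or any 1 of the CR replicates (from 0.0569 to 0.0818). In the same CR libraries 6 of 17 microglia markers were higher (median log2 fold change 0.33), and the summed markers of the 5 caudal regions stood at 226 to 291 FPKM, against 15.7 to 31.8 FPKM in control. Thyroid hormone response genes had 2 higher, 6 lower and 4 not past the threshold (2 and 6 adjusted over the list alone; camera adjusted p = 0.109, 0.0331 with no filter on low values, and adjusted p = 0.414 with an estimated correlation). Itih3 rose from 3.68 ± 1.40 to 9.29 ± 2.07 FPKM, and Dio2, the deiodinase that activates thyroid hormone, fell from 2.59 ± 0.132 to 1.00 ± 0.182 FPKM. Nr4a2, Nr4a3, Bcl6 and Dio2 fell in the libraries in which dorsal telencephalic markers were lower.

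**Figure D3:**
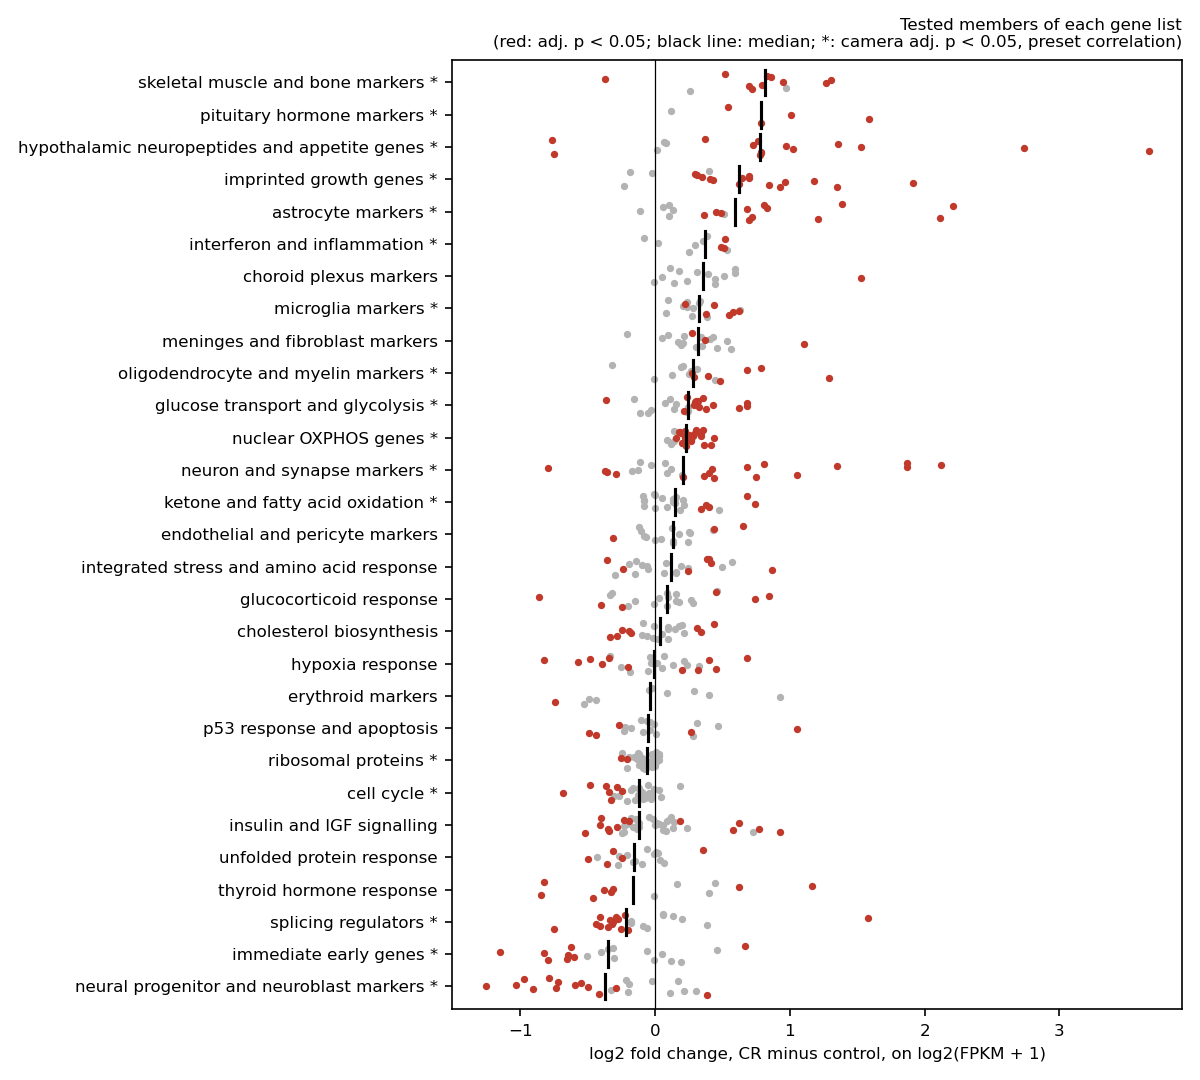
Each row is 1 of the 29 gene lists tested, each point a tested member placed by its log2 fold change (CR minus control, on log2 of FPKM plus 1), red where its adjusted p was under 0.05, with the median as a black line. The 17 lists with an asterisk passed camera with a preset correlation, 12 of them upwards and 5 downwards, and 0 passed with an estimated correlation.

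RNA of the Y chromosome differed between libraries of a group. Eif2s3y was at 43.4 FPKM in control replicate 3, 42.6 in CR replicate 1 and 38.9 in CR replicate 3, and at 0 FPKM in control replicates 1 and 2 and in CR replicate 2, and Kdm5d was above 0 in the same 3 libraries (adjusted p = 0.496 and 0.506 between the groups). Y-linked RNA was thus present in 1 of 3 control and 2 of 3 CR libraries. The list of Y-linked genes and Xist had 2 tested members and the list of nuclear-retained noncoding RNAs had 0, so neither was tested as a list. In a principal component analysis the first component held 61.8% of the variance and separated control (-28.7 to -20.5) from CR (19.96 to 26.4). Pearson correlations across genes, which are not independent replicates, ranged from 0.986 to 0.990 within control, from 0.991 to 0.992 within CR and from 0.967 to 0.975 between the groups.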

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

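The limma-voom test and the Y-linked covariate were chosen after the data had been seen. The count of 5173 genes lay between 4445 and 5779 in the settings that used all 6 libraries, and genes called both there and in the main test had the same direction in each of them. Leaving out 1 library gave 3210 to 5042 genes (1668 to 2698 higher and 1542 to 2344 lower), with fewer samples in each fit. The share of higher genes, 52.3% in the main test, was 46.9% with quantile normalization and 56.0% with no filter on low values. Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at 0.024, 0.020 and 0.045. Each was above the correlations with other numbers (highest 0.017), a hint from the data and not from the design, and a replicate block gave 4445 genes (2352 higher and 2093 lower), 4266 of them shared with the main test, with an adjusted p of 0.115 for Insr.

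Insr passed the threshold with limma-voom (-0.30, adjusted p = 0.0259) and with the Y-linked covariate (-0.30, adjusted p = 0.0354), with an adjusted p from 0.0259 to 0.208 over all settings, and its log2 fold change lay between -0.29 and -0.19 when 1 library was left out. The cause was not tested. Of the 17 lists called, 0 passed camera in limma with an estimated correlation, where 2 lists had an unadjusted p under 0.05. The estimate was above the preset 0.01 in each of the 17 except interferon and inflammation (-0.016). That list's unadjusted camera p still rose from 0.00844 to 0.0514, so a higher correlation does not account for its lost call. The glycolysis list, with an estimate of only 0.017, went from 7.26e-05 to 0.0206. With an estimated correlation, camera also takes p from the few residual degrees of freedom of the 6 libraries. With a preset one it takes p from about as many as there are genes. That difference raises p at any correlation, so the lost calls do not by themselves show that members vary together. The share of each part in the lost calls was not separated. Some uncalled results turned their direction. The glucocorticoid list did so with a mean of at least 2 FPKM (adjusted p = 0.80). Leaving out 1 library turned it and the erythroid, hypoxia and cholesterol lists, with adjusted p from 0.60 to 0.995, 0.161 to 0.979, 0.633 to 0.979 and 0.391 to 0.947, and the log2 fold changes of Slc2a3 (-0.20 to 0.028) and Slc2a1 (-0.17 to 0.0079). The cause was not tested. With the Y-linked covariate the log2 fold changes of Eif2s3y and Kdm5d were -0.046 and -0.040, since that covariate was made from Y-linked genes. Genes at or under 3 reads per library are limited by depth.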

Other observations

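The region markers were listed, and the genes of the next paragraph, limma-voom, the Y-linked covariate and the test of growth on reads in control were chosen, after the main comparison had been seen.

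Several neuroendocrine genes outside the rule for named genes, chosen after their values were seen, were also higher in CR (means ± SD over 3 libraries, limma adjusted p). They were not tested as a set. Nap1l5, an imprinted nucleosome assembly gene, was at 50.3 ± 10.6 FPKM in control and 269.7 ± 21.5 in CR (adjusted p = 0.000133). Hap1, the huntingtin-associated protein gene, was at 15.4 ± 8.94 and 76.8 ± 5.62 FPKM (0.00226), and the secretogranin gene Scg2 at 14.1 ± 2.17 and 53.4 ± 4.49 FPKM (0.000136). The calcitonin receptor gene Calcr was at 1.00 ± 0.696 and 10.6 ± 1.33 FPKM (0.000745). Among monoamine genes, the decarboxylase gene Ddc was at 0.663 ± 0.224 and 4.66 ± 0.417 FPKM (0.000301) and the serotonin transporter gene Slc6a4 at 0.224 ± 0.0899 and 4.56 ± 0.762 FPKM (0.000161). In the other direction, the transcription factor gene Tcf4 was at 82.3 ± 1.48 and 38.6 ± 4.55 FPKM (0.000388).

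Of 55 markers of regions caudal to the telencephalon, 27 (49.1%) had at most 3 reads in every control library, while others did not, such as Tcf7l2 with 91, 1421 and 949 reads in control replicates 1 to 3, and the labels call both groups whole brain. Depth was argued against, since CR replicate 1 was above the more deeply sequenced control replicate 2 by a median log2 ratio of 3.39 over the 55 markers (lowest of all library pairs 2.92). An effect of caloric restriction on regional growth was argued against as the whole cause by that 49.1%, since it would leave the brains of normally fed pups whole, and a contribution of it to the CR values stays open and untested. A candidate explanation is that control libraries held less tissue caudal to the telencephalon. Of 35 caudal markers whose values had not been seen when they were listed, 100% had all 3 CR values above all 3 control values. Any cause that sets caudal RNA higher in CR would give the same, so this result does not tell the candidate from other causes. The 35 are also not independent of the markers that had been seen. The median log2 ratio was -0.73 for 14 ventral telencephalic markers and -1.22 for 10 dorsal ones. A smaller share of telencephalon as a whole in the CR libraries would lower both. The unequal fall was not explained, nor were the higher CR values of the ventral marker Six3, which did not pass the threshold (limma adjusted p = 0.0741). A difference in the tissue held would go with the groups, so the 5173 calls, the values of Insr, Igf1r and Igf2 and the list results cannot be separated from it.

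Y-linked RNA was present in 1 control and 2 CR libraries, so pup sex could have contributed to the calls. With presence of Y-linked RNA as a covariate, 4705 genes passed, 4422 of them shared with the main test. The median ratio of log2 fold changes over the 5173 called genes, with over without the covariate, was 1.01, and 5173 of 5173 kept their sign. These genes had been called with group as the only term, a test that Eif2s3y did not pass (limma adjusted p = 0.496). Genes that follow Y-linked RNA closely were thus unlikely to be among them, so the ratio does not decide whether sex contributed.

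In CR 12 of 18 astrocyte and 7 of 16 oligodendrocyte markers passed as higher and 12 of 22 progenitor and neuroblast markers as lower, but only 1 of 4 tested telencephalic progenitor markers did (Neurog2), and a more mature telencephalon in CR may be considered. It would lower telencephalic progenitor markers further than dorsal telencephalic markers in general, but their median log2 ratio (-0.25 over 5 genes) was 0.97 above that of the dorsal markers. The progenitor genes are few, some are also expressed outside the telencephalon, and Neurog2 lay inside the range of the dorsal markers (-1.68 to -0.67), so this value does not settle the question. Maturity and the share of each region cannot be told apart for these genes.

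Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 5173 genes and the highest of the others gave 5. A share under 0.05 cannot be reached with 10 splits. Each of the other splits also mixes control and CR libraries, so the difference between the groups adds to the spread within its sets of 3. Low counts there therefore do not gauge how many calls chance would give.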
